A study of Mus musculus with 10 samples.

How the data were processed

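Ileum, the last part of the small intestine, was profiled on Illumina mouse bead arrays in 5 wild-type (WT) and 5 interferon-gamma (IFNg) knockout male C57Bl/6 mice aged 8 weeks, kept specific-pathogen free on standard chow. Per the labels' protocols, tissue was homogenised with ceramic beads, total RNA was taken on silica columns and amplified into biotin-labelled RNA, 1 array per sample. The labels place 2 WT and 2 knockout samples in array set 1, and 3 of each in array set 2. Each sample carries a number of its own in its title, and samples are named by these titles. The labels do not state outright that each number is a separate animal, so p-values measure the spread between these 10 samples.

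The deposited table of non-normalised values holds, per the file headers and the values, a linear intensity per probe and array without background subtraction, and a detection p-value, the share of negative control signals at or above that of the probe. The authors' value table of the same arrays holds linear intensities that are quantile normalised without background subtraction, as read from the values, since sorted intensities agree between arrays and ranks within an array match the non-normalised ones. Its scale and direction are therefore known. The submitters' processing notes name lumi, with no version or role, and the scanner software is not given in the sources used here.

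From the non-normalised intensities, background was corrected by normexp with control means inferred from the detection p-values, an offset of 16 was added, and arrays were quantile normalised on the log2 scale (neqc, limma 3.58.1 in R 4.3.3). Of 25697 probes, 12039 had a detection p under 0.05 on at least 5 arrays and were tested. Gene names came from the platform table, updated through the Entrez identifier or accession with a mouse RefSeq gene table of assembly GRCm38.p6. On the array, 23978 probes have 1 gene symbol, 0 have several and 1719 are unnamed here. The gene table matched 23971 named probes and missed 7, and 8 symbols were updated. The files name no genome build, so chromosomes and neighbourhoods are taken from the gene table and no coordinates are printed. The tested probes covered 8685 genes, and 674 of them had no gene name. A gene with several probes is represented by the probe with the highest mean.

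Knockout and wild type were compared with limma (lmFit and eBayes), with array set as an additive term, and adjusted by Benjamini-Hochberg at 5%. Differences are log2 knockout minus wild type with the standard error (SE) of the fit, and levels are log2 means ± SD with n = 5 per group. Where a gene was detected on no array of a group, the ratio is given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the gene's own signal. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule names Ifng, probes past 5% with 1 gene and the same sign in both array sets, the 5 genes per direction with the lowest p where fewer than 12 pass, the 4 members of each list with the lowest p, and the gene flanking Ifng with the lowest p. The genes given below are a part of those it names, and the rule did not fix which of them are given. Genes outside the rule are said to be chosen after their values were seen.

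Gene lists came from textbook knowledge, 36 in all, of which 35 had at least 5 measured members. They cover interferon and antigen presentation, epithelial and immune cell types, the gut wall, lipid and xenobiotic metabolism, clock, cell cycle and stress genes, and pancreas, fat and blood as possible admixtures. Each was compared with the remaining genes by camera, two-sided, with a preset inter-gene correlation of 0.01, and adjusted over the lists. Alternatives estimated that correlation from the data, or used fry, whose p tests whether a list's genes move on balance one way and whose mixed p tests change in either direction. Single members are also given adjusted over the list alone. Genes within 20 Mb of Ifng were compared with the rest by a two-sided Fisher's exact test, array measures by two-sided exact permutation tests, and the genotype effects of the 2 array sets by an interaction term.

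The alternatives changed the background correction, the normalisation, the values used, the filter on dim probes, the handling of array set, the variance model, array weights, the probe summary, the threshold and the test, and left out each sample in turn. No sample was left out of the main comparison. The steps were tested on simulated data with the real probes' means, array set effects and residual spreads, independent between genes. Of 50 probes each changed by 0.5, 1, 1.5 and 2 log2 units among 12039, 26%, 76%, 96% and 98% were called, as were 7 of 11839 unchanged ones. All changed probes were simulated together, and many true changes loosen the Benjamini-Hochberg threshold. These shares therefore do not carry over to the real comparison, where 2 probes passed and the threshold was stricter. In the same simulation 3 of 3 lists shifted by 0.3 and 0 of 32 unshifted lists were called. Because the simulated genes were independent, this does not show how often lists of correlated genes are called falsely. The number of arrays limits the precision.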

Results

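The series addressed the effect of IFNg deficiency on gene expression in the mouse ileum. IFNg is the cytokine made by T and natural killer cells that drives macrophage activation and antigen presentation. The arrays of the 5 WT and 5 knockout samples detected 10618 to 12975 probes each, with a median raw intensity of 93 to 112. The first principal component held 44% of the variance and parted the 2 array sets, and 2316 probes differed between the sets past 5% (limma), so array set was fitted throughout. Ileum_WT_641 stood apart from the other arrays, with the fewest probes detected (10618), the lowest mean correlation with the others (0.949) and an array weight of 0.28. Ileum_WT_644 had the lowest median raw intensity (93) and the lowest mean raw intensity (500.2), with 10818 probes detected and an array weight of 0.87.

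Ifng itself gave no signal above background in any sample. Its 2 probes had mean raw intensities of 83.6 ± 9.8 and 89.8 ± 14.9 (SD, n = 5) in WT and of 87.2 ± 4.2 and 83.6 ± 9.0 (n = 5) in the knockout. The lowest detection p of either was 0.0977 in WT and 0.144 in the knockout. Neither probe was tested, so these arrays do not check the genotype labels.

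Fbln2, which encodes the extracellular matrix protein fibulin-2, was the 1 named gene that changed past 5%, and it fell. Its log2 level was 7.57 ± 0.40 in WT and 5.29 ± 0.36 in the knockout (SD, n = 5 each), a difference of -2.28 ± 0.21 (SE) with an adjusted p of 0.000876. All 5 knockout samples lay below all 5 WT samples, and the difference was -2.59 in array set 1 and -2.08 in array set 2. Fbln2 lies on chromosome 6. It was detected on 5 of 5 WT arrays but 1 of 5 knockout arrays. The size of its fall varied with the processing, at -1.17 where no background was subtracted and -1.28 in the authors' value table. Its other 2 probes were not detected on any array. The call was lost in array set 1 alone (adjusted p = 0.363) and in array set 2 alone (0.108), and the adjusted p ranged from 0.000155 to 0.363 over 26 alternatives.

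A second probe, ILMN_1216322, which is unnamed here, also fell, from 10.07 ± 0.56 in WT to 8.43 ± 0.14 in the knockout (SD, n = 5 each; difference -1.65, adjusted p = 0.0324, limma). It was lower in every knockout sample, at 8.23 to 8.62 against 9.54 to 11.02. Its call was lost without any one sample other than Ileum_WT_642 and Ileum_WT_643, with adjusted p-values of 0.0557 to 0.139. It was also lost without the array set term (0.0678), without the filter on dim probes (0.227), in array set 1 alone (0.902) and in array set 2 alone (0.382), the whole range being 0.0036 to 0.902.

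No probe rose past 5% among the 12039 tested with limma. At an unadjusted p under 0.05 there were 706 higher and 768 lower probes, 1474 in all, where 602 would be expected if no probe differed, and 49 had a p under 0.001, where 12 would be expected. Probes are not independent, and when the samples were split into other groups of 5 and 5, 4 of 100 splits, the real one included, gave as many probes at an unadjusted p under 0.05, with a median of 468 and a highest count of 2190 in the others. The next genes by p on the higher side were Clspn, the replication checkpoint adaptor claspin (0.73 ± 0.12, SE), Lss, the lanosterol synthase of the cholesterol pathway (1.11 ± 0.18), Dbp, a transcription factor of the clock's output (1.05 ± 0.18), Gsta3, a glutathione transferase (1.14 ± 0.21), and Thg1l, a tRNA-modifying enzyme (0.64 ± 0.12, detected on 2 of 5 WT arrays). Their adjusted p-values were 0.107 for Clspn and Lss, 0.144 for Dbp and 0.175 for Gsta3 and Thg1l. The other 2 tested Clspn probes showed differences of 0.05 and 0.43. On the lower side came Uroc1, the urocanase of histidine breakdown (-0.84 ± 0.16), Txk, a T cell kinase (-0.64 ± 0.12), Mt2, a metallothionein (-1.10 ± 0.22), Tm4sf20 (-0.84 ± 0.17) and Pcyt1a, an enzyme of phosphatidylcholine synthesis (-0.85 ± 0.17), all with an adjusted p of 0.175. Txk was detected on 0 of 5 knockout arrays and was at least 1.36-fold higher in WT. Clspn, Lss and Dbp passed 5% in 6, 5 and 4 of 27 alternatives each, with adjusted p-values reaching 0.902 in others.

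**Figure D1:**
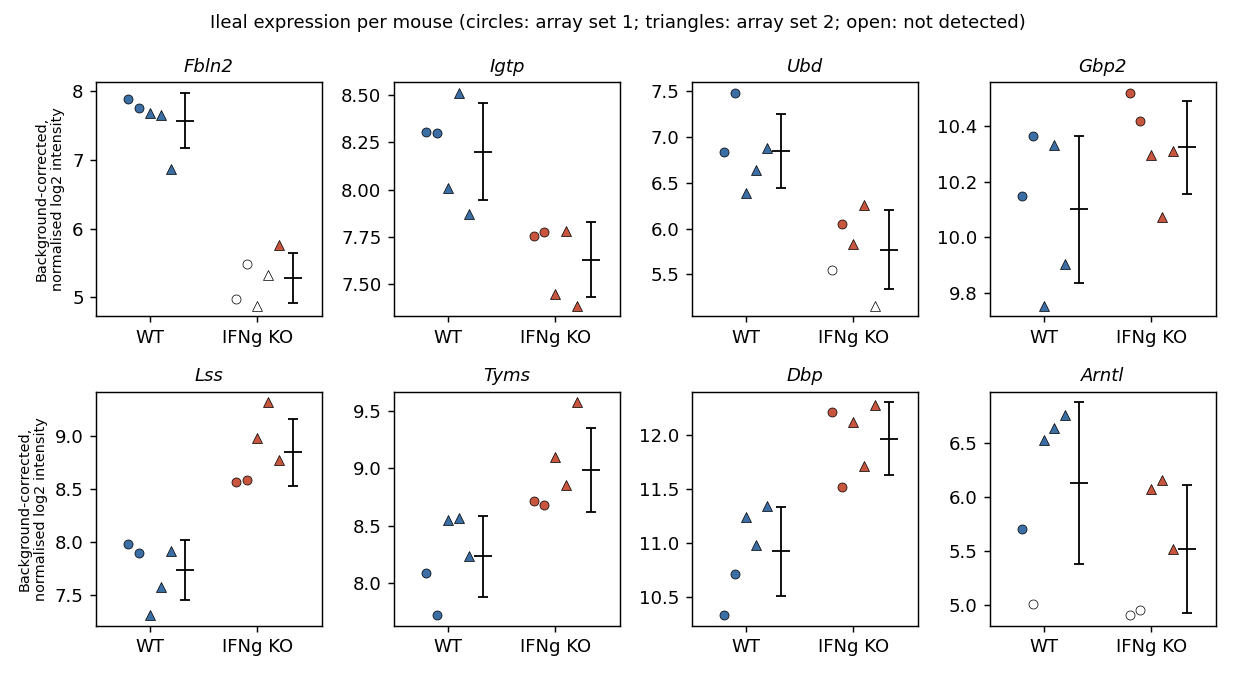
Normalised log2 intensity of 8 genes per mouse in WT (blue) and knockout (red) ileum, circles for array set 1, triangles for array set 2, open symbols where the probe was not detected, and bars for mean ± SD (n = 5). Fbln2 lies at 6.87 to 7.88 in WT and 4.88 to 5.76 in the knockout, while the 2 groups overlap for Gbp2 and Arntl.

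The interferon-inducible GTPases, proteins of cell-autonomous immunity that IFNg is known to induce, did not pass as a group. Of 19 listed genes 17 are on the array and 8 were measured, the others on it failing the filter on dim probes. Of the 8 measured members 5 were higher and 3 lower. The list gave a median of 0.03, a mean of -0.002, a downward test direction and an adjusted p of 0.999 (camera). None passed 5% over all probes, and Igtp alone did so adjusted over the list alone (-0.57 ± 0.15, SE, adjusted p = 0.0142). All 5 knockout samples lay below all 5 WT samples for Igtp. Gbp3 differed by 0.30 ± 0.15, Gbp2 by 0.22 ± 0.14 and Irgm2 by -0.18 ± 0.13, the last turning to 0.02 under median scaling, which shifted the median of all tested probes by 0.19. The mixed fry test of the list had an adjusted p of 0.0082.

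The wider list of IFNg signalling genes and direct targets showed 16 of 29 measured members lower and 13 higher, with a median of -0.09 and an adjusted p of 0.471; its median was 0.14 under median scaling and its mixed fry test had an adjusted p of 0.0345. Over all probes 0 members passed 5% (limma), and Ubd and Ccl5 did adjusted over the list alone. Ubd, a ubiquitin-like protein induced by inflammatory cytokines, was lower by -1.07 ± 0.22 (SE) and was detected on 3 of 5 knockout arrays. Ccl5, a chemokine of cytotoxic lymphocytes, was higher by 0.89 ± 0.19 and was detected on 3 of 5 arrays in each group. Ifngr2, a chain of the IFNg receptor, differed by -0.38 ± 0.15 (-0.72 in array set 1 and -0.16 in array set 2). Il18bp differed by -0.42 ± 0.20 (-0.90 and -0.10 in the sets, and -0.27 without Ileum_IFNgKO_645). The antigen presentation lists gave adjusted p-values of 0.52 for MHC class I (median -0.07, or 0.10 under median scaling) and 0.625 for class II (median 0.01). Leaving out 1 sample in turn put these medians at -0.14 to -0.03 and -0.06 to 0.10, and that of the IFNg targets at -0.12 to -0.03. Within class I, H2-Q7 (-0.54 ± 0.15) and Tap2 (-0.45 ± 0.17) were lower and H2-M3 (0.48 ± 0.15) and Pdia3 (0.38 ± 0.14) higher, and 0 of 22 members passed 5% by either adjustment. Type I interferon-stimulated genes had a median of 0.15 (adjusted p = 0.0812; mixed fry 0.0256; -0.04 in array set 1 and 0.28 in array set 2; 0.0476 without Ileum_IFNgKO_645, 0.0491 without Ileum_IFNgKO_647, 0.044 without Ileum_IFNgKO_649, 0.0148 in array set 2 alone, 0.0172 without the filter on dim probes and 0.0326 with a stricter one; median 0.05 and 0.472 without Ileum_IFNgKO_648), with Ifit2 at 0.57 ± 0.17 and Ifi27l2a at 0.76 ± 0.23. A second Ifit2 probe showed no difference (-0.0005).

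Of the 35 lists tested 10 passed 5%, 7 higher and 3 lower in the knockout, with array set fitted. With an estimated inter-gene correlation 0 passed and 2 had an unadjusted p under 0.05, and with fry 0 passed and 5 had an unadjusted p under 0.05. The mixed fry test, which asks for change in either direction and does not compare a list with other genes, passed 12 lists, 6 of them among the 10. When the 10 samples were split into other groups of 5 and 5, 12 of 100 splits, the real one included, gave as many lists. The median of the other splits was 6 lists.

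Cholesterol synthesis genes, targets of the transcription factor SREBP-2, rose as a list in the knockout. Of 19 measured members 16 were higher, with a median of 0.49 and a mean of 0.44 (camera adjusted p = 3.51e-08; adjusted p = 0.617 with an estimated correlation; range over alternatives 4.03e-11 to 0.617). Over all probes 0 passed 5%, and 8 did adjusted over the list alone, all higher. They included Lss, Aacs, which activates acetoacetate for sterol synthesis (0.73 ± 0.19, SE), Insig1, a feedback regulator of SREBP processing (0.65 ± 0.17), and Fdps, the farnesyl diphosphate synthase (0.53 ± 0.15). The Aacs difference was 0.21 in array set 1 and 1.08 in array set 2. The list's median was 0.33 in array set 1 and 0.60 in array set 2, and it stayed between 0.40 and 0.56 without any 1 sample. Unadjusted, the camera p was 1e-09 for the real split into 5 and 5. It was lower, at 4.17e-13 and 2.41e-11, in other splits, which held array set 1 unevenly. The camera p alone therefore does not set genotype apart from other groupings of the samples.

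Genes of fat absorption and chylomicron assembly fell as a list, with 15 of 20 lower and a median of -0.26 (adjusted p = 0.00655; adjusted p = 0.659 with an estimated correlation; range over alternatives 5.97e-07 to 0.994). Under median scaling the list's median was -0.08, against 0.19 for all probes (camera adjusted p = 0.000947). No member passed 5% by either adjustment. Apoa4 was at -1.21 ± 0.47 (SE), with -0.45 in array set 1 and -1.71 in array set 2. Apoc2 was at -0.52 ± 0.19 and Mttp, which loads fat onto chylomicrons, at -0.34 ± 0.14. The list's median was -0.10 in array set 1 and -0.33 in array set 2, and its call was lost without Ileum_IFNgKO_649 (median -0.15, adjusted p = 0.0829) and in array set 1 alone (0.994). PPARa targets and fatty acid oxidation genes also fell as a list, with 21 of 29 lower and a median of -0.13 (adjusted p = 0.0336; adjusted p = 0.617 with an estimated correlation; range over alternatives 0.000934 to 0.617), although under median scaling the median was 0.07, which lay below the 0.19 of all probes (adjusted p = 0.0241). Acot1, an acyl-CoA thioesterase (-0.66 ± 0.16), passed adjusted over the list alone, while Pdk4 (-0.63 ± 0.21) and Angptl4 (-0.73 ± 0.25) did not. The call was lost without Ileum_WT_640 (adjusted p = 0.115), Ileum_WT_643 (0.0827), Ileum_IFNgKO_647 (0.0597) or Ileum_IFNgKO_649 (0.0586), without the filter on dim probes (0.126) and in array set 1 alone (0.57), and the median was -0.08 without Ileum_IFNgKO_648 (0.0358).

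Cell cycle genes rose as a list, with 29 of 32 higher and a median of 0.25 (adjusted p = 1.25e-06; adjusted p = 0.617 with an estimated correlation; range over alternatives 6.87e-09 to 0.617). The median was 0.26 in array set 1 and 0.27 in array set 2. Tyms, the thymidylate synthase (0.75 ± 0.15, SE), and Mcm4, a subunit of the replicative helicase (0.44 ± 0.12), passed 5% adjusted over the list alone. The other tested Tyms probe differed by 0.37, and Rrm1, of ribonucleotide reductase, was at 0.49 ± 0.15. Leaving out any 1 sample kept the adjusted p at 0.000206 or below, but 7 of 100 splits of the samples into 5 and 5, the real one included, gave a mean difference as large as the real 0.23. The other 6 held array set 1 unevenly, and permuted within array sets the mean had an exact p of 0.0167, the smallest that 120 assignments allow (two-sided).

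Circadian clock genes moved both ways. Of 17 measured 12 were higher, with a median of 0.23 (adjusted p = 0.0452; adjusted p = 0.617 with an estimated correlation; range over alternatives 0.00454 to 0.617), and 4 higher and 2 lower ones passed 5% adjusted over the list alone. Dbp and Per3 (0.85 ± 0.22, SE) were higher, whereas Arntl, the activator of the clock loop (-0.61 ± 0.17), and Nfil3, the repressor that opposes Dbp (-0.89 ± 0.24), were lower. Arntl was detected on 4 of 5 WT and 3 of 5 knockout arrays. The list's call was kept in 7 of 27 alternatives, and it was lost without any one sample other than Ileum_WT_644 and Ileum_IFNgKO_647, with adjusted p-values of 0.0506 to 0.146.

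**Figure D2:**
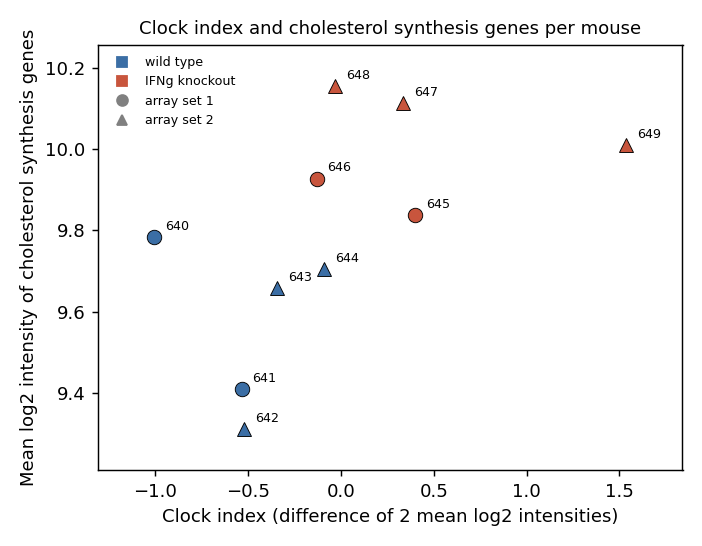
Mean log2 intensity of the cholesterol synthesis genes against a clock index, the mean log2 intensity of 9 clock genes such as Dbp minus that of 4 such as Arntl, per sample (blue WT, red knockout, circles array set 1, triangles array set 2, sample numbers as in the labels). The index was -0.50 ± 0.34 in WT and 0.42 ± 0.66 in the knockout (SD, n = 5), with Ileum_IFNgKO_649 highest at 1.53.

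**Figure D3:**
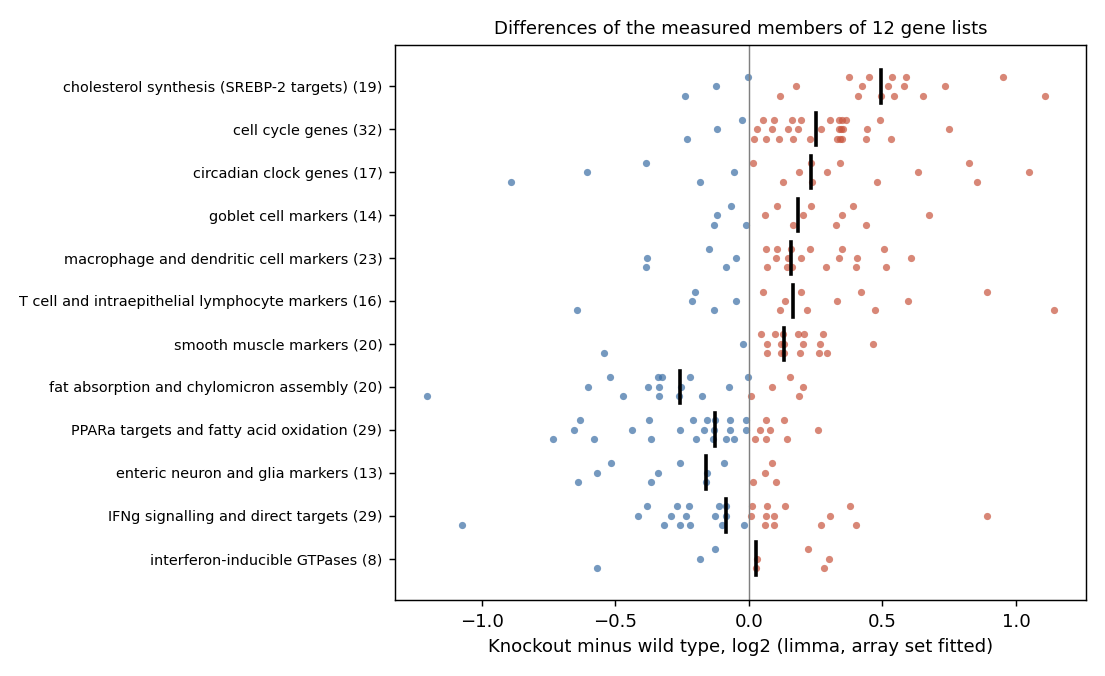
Knockout minus wild-type log2 difference of each measured member (point, red above 0 and blue below) of 12 gene lists, with the list's median as a black bar and the number of members in brackets. The median is 0.49 for cholesterol synthesis genes, -0.26 for fat absorption genes and 0.03 for the interferon-inducible GTPases; under median scaling the medians of the PPARa and IFNg target lists were above 0.

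Markers of 5 cell types or groups also passed as lists. Macrophage and dendritic cell markers were higher (18 of 23, median 0.16, adjusted p = 0.0185; adjusted p = 0.617 with an estimated correlation; range over alternatives 0.000473 to 0.617), among them Fcgr3 (0.61 ± 0.16, SE, detected on 1 of 5 WT and 5 of 5 knockout arrays), the complement gene C1qb (0.51 ± 0.15) and the mannose receptor Mrc1 (0.51 ± 0.16). Goblet cell markers were higher (10 of 14, median 0.18, adjusted p = 0.0336; adjusted p = 0.617 with an estimated correlation; range over alternatives 0.00794 to 0.617), with the chemokine gene Ccl9 (0.67 ± 0.17) passing adjusted over the list alone and Spink4 at 0.39 ± 0.12. T cell and intraepithelial lymphocyte markers were higher (11 of 16, median 0.17, adjusted p = 0.0452; adjusted p = 0.659 with an estimated correlation; range over alternatives 0.0112 to 0.659). In that list Cd8b1, a chain of the CD8 co-receptor (1.14 ± 0.24, detected on 1 of 5 WT and 4 of 5 knockout arrays), and Cd3d (0.47 ± 0.14) were higher and Txk was lower. Smooth muscle markers were higher (18 of 20, median 0.13, adjusted p = 0.0452; adjusted p = 0.741 with an estimated correlation; range over alternatives 6.13e-07 to 0.741), but their median was -0.18 in array set 1 and 0.37 in array set 2. The member with the lowest p, Cald1, was lower (-0.54 ± 0.21). The next by p, Tagln, Tpm1 and Tpm2, were lower in array set 1 (-0.198 to -0.007) and higher in array set 2 (0.482 to 0.905). Enteric neuron and glia markers were lower (9 of 13, median -0.16, adjusted p = 0.0366; adjusted p = 0.659 with an estimated correlation; range over alternatives 0.000196 to 0.692), with Npy at -0.64 ± 0.18 and Uchl1 at -0.57 ± 0.18, and their median was -0.55 in array set 1 and -0.02 in array set 2.

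These cell type calls were lost when certain single samples were left out. The macrophage call was lost without Ileum_WT_640 (adjusted p = 0.101) or Ileum_WT_643 (0.062), and the goblet call without Ileum_WT_642 (0.0667), Ileum_IFNgKO_646 (0.0547) or Ileum_IFNgKO_649 (0.0923). The T cell call was lost without Ileum_WT_640, Ileum_WT_642, Ileum_WT_643, Ileum_IFNgKO_646, Ileum_IFNgKO_647 or Ileum_IFNgKO_649, with adjusted p-values of 0.0597 to 0.194, and its median was 0.08 without Ileum_WT_640 and 0.25 without Ileum_WT_641. The smooth muscle call was lost without Ileum_WT_640, Ileum_WT_643, Ileum_WT_644, Ileum_IFNgKO_647, Ileum_IFNgKO_648 or Ileum_IFNgKO_649 (0.0749 to 0.677), and its median was 0.04 without Ileum_WT_644, 0.27 without Ileum_WT_641, 0.20 without Ileum_WT_642 and 0.22 without Ileum_IFNgKO_645. The neuron call was lost without Ileum_WT_640, Ileum_WT_641, Ileum_WT_642, Ileum_WT_643, Ileum_IFNgKO_645 or Ileum_IFNgKO_646 (0.0526 to 0.236), and its median was -0.09 without Ileum_WT_641, the array with the fewest probes detected, or Ileum_IFNgKO_645, -0.31 without Ileum_WT_644 and -0.24 without Ileum_IFNgKO_647. Median scaling ended the goblet (0.0683), T cell (0.152) and smooth muscle (0.175) calls.

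The remaining cell type lists did not pass in the main comparison, and some did under an alternative. Fibroblast and matrix genes, the list that holds Fbln2, had 20 of 25 members higher and a median of 0.17 (adjusted p = 0.108), and they passed without Ileum_WT_643 (0.0473) or Ileum_IFNgKO_647 (0.032). Paneth cell and antimicrobial genes had a median of -0.08 (adjusted p = 0.198; 0.0196 with median scaling, 0.0481 with cyclic loess and 0.0202 in array set 2 alone), mature enterocyte markers one of 0.01 with a mean of -0.02 and a downward test direction (adjusted p = 0.709; median -0.12 and adjusted p = 0.0434 without Ileum_WT_641, the array with the fewest probes detected), intestinal stem cell markers 0.09 (0.621) and tuft cell markers -0.11 (0.121, with a median of 0.07 under median scaling). Ileal bile acid and cobalamin uptake genes were at -0.13, or 0.02 under median scaling (adjusted p = 0.471), and proximal small intestine markers at 0.16 (0.696). Plasma cell markers were at a median of 0.01 and a mean of 0.21 (0.267; 0.0367 in array set 1 alone), neutrophil markers at -0.15 (0.209; 0.0219 with median scaling), endothelial markers at -0.07 (0.709; 0.13 under median scaling), and type 2 immune and mast cell genes at a median of -0.02, or 0.18 under median scaling, with a mean of 0.005 and a downward test direction (0.999). IL-17 and IL-22 response genes were at -0.07 (0.237; 0.026 with median scaling) and unfolded protein response genes at 0.11 (0.444; 0.0191 in array set 1 alone). Of the 6 measured type 2 and mast cell genes, 1 higher and 2 lower passed 5% adjusted over the list alone. The higher one was Prg2, detected on 0 of 5 WT and 5 of 5 knockout arrays. The lower ones were Il13 (-0.43 ± 0.16, SE) and Cpa3 (-0.48 ± 0.17). By the same adjustment Mmp9 (-0.78 ± 0.23) passed in the neutrophil list and Dnajb9 (-0.62 ± 0.17) in the unfolded protein response list. Pancreatic acinar genes were at -0.03, or 0.10 under median scaling (0.728), and 2 erythrocyte genes, too few to test, at -0.51. Adipocyte genes had a median of 0.20 and a mean of 0.38 (0.198; 0.0473 without Ileum_WT_643 and 0.0127 without Ileum_IFNgKO_647; median 0.01 and 0.781 without Ileum_WT_642), with Thrsp, a lipogenic regulator, highest at 1.62 ± 0.57 (SE). Leaving out 1 sample in turn put the median at 0.02 to 0.26 for proximal small intestine markers, 0.04 to 0.11 for stem cell markers, -0.14 to -0.03 for tuft cell markers, -0.21 to -0.05 for neutrophil markers, 0.10 to 0.22 for fibroblast genes, 0.05 to 0.15 for unfolded protein response genes and -0.14 to -0.07 for bile acid and cobalamin uptake genes. The same range was -0.28 to -0.02 for IL-17 and IL-22 response genes and -0.16 to -0.05 for Paneth cell and antimicrobial genes.

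Genes near Ifng on chromosome 10 were compared with the rest because a knockout line can keep donor sequence around the targeted gene. Of 106 tested genes within 20 Mb of Ifng 0 passed 5%, against 1 of 8578 elsewhere (two-sided Fisher's exact p = 1). Since the 1 gene past 5% was Fbln2, on another chromosome, this comparison could show no excess near Ifng. At an unadjusted p under 0.01 there were 5 of 106 near it and 296 of 8578 elsewhere (Fisher's exact p = 0.419). The fixed list of genes flanking Ifng had a median of -0.02, or 0.16 under median scaling (camera adjusted p = 0.709), and the flanking gene with the lowest p was Slc35e3, on chromosome 10 (-0.35 ± 0.12, SE, adjusted p = 0.308).

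The arrays of the 2 genotypes were close in overall signal. Median raw intensity was 105 ± 7.27 in WT and 107 ± 4.3 in the knockout (SD, n = 5 each, two-sided exact permutation p = 0.683), and 11476 ± 781 and 12197 ± 622 probes were detected (exact permutation p = 0.151). The interquartile range of raw log2 intensity was 1.77 ± 0.23 in WT and 2.01 ± 0.21 in the knockout (n = 5 each, exact permutation p = 0.135). Permuted within array sets it differed by 0.23 with an exact p of 0.0167, the smallest that the 120 assignments allow for a two-sided test. The smallest p that the unrestricted test can give is 0.0079, which no measure reached. Adjusted over the 3 measures, its p-values were 0.683, 0.226 and 0.226. No probe differed in its genotype effect between the array sets past 5% (limma interaction term; 382 at an unadjusted p under 0.05 against 602 expected), and the fold changes of the 2 sets correlated with a Pearson r of 0.336 across probes, which are not independent replicates.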

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

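The test of genes around Fbln2 was chosen only after the result was seen. Of 126 groups of 5 values examined, 2 held a value far from the others, and chance alone marks about 1 in 20 groups. Ileum_WT_644 had a log2 Fbln2 value of 6.87, where the other 4 WT samples lay at 7.66 to 7.88. Ileum_WT_640 had a log2 Clspn value of 7.83, where the other 4 lay at 7.66 to 7.69.

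Fbln2 was the 1 named gene past 5%, and all 5 knockout values lay below all 5 WT values, the low one of Ileum_WT_644 included. Uroc1, lower by -0.84 without passing 5% (adjusted p = 0.175), lies near it on chromosome 6, so a chromosome segment that differs between the 2 lines of mice might account for both. Of 47 other tested genes within 5 Mb of Fbln2, 1 had an unadjusted p under 0.01 (2.1%), against 298 of 8635 elsewhere (3.5%; Fisher's exact p = 1), which gives no sign of a wider segment, but fewer genes were tested than the 50 set as the minimum to exclude one. A probe that fails on the sequence of 1 line could not be told apart from lower expression either, because 0 of the other 2 Fbln2 probes gave a signal above background. An effect of the IFNg genotype stays open as well, and no test here separates it from a difference between the lines.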

How the results depend on the processing

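None of the alternatives was chosen after the results were seen. The count of probes past 5%, 2 with the main settings, was 5 with normexp without detection p-values (3 higher, 2 lower) and 5 in the authors' value table (3 higher, 2 lower). Under median scaling it was 10, with 8 higher and 2 lower against 0 and 2; that scaling moved the median of all tested probes by 0.19 and put 78.8% of them above 0 against 51%. It was 4 with trend and robust variance (2 higher, 2 lower), 1 without the array set term, 1 with Welch's test per probe (Clspn, higher, with Fbln2 at an adjusted p of 0.0852 and the unnamed probe at 0.706), and 0 with array set 1 or array set 2 alone (limma; 530 and 888 at an unadjusted p under 0.05), where fewer samples were fitted; leaving out each sample gave 1 to 3. Fbln2 passed in 23 of 26 alternatives, with differences from -2.59 to -1.17 and adjusted p-values from 0.000155 to 0.363, and the unnamed probe in 14 of 27 (0.0036 to 0.902). The count of gene lists, 10 with the main settings, was 6 with array set 1 alone, 3 of them among the 10, 0 with an estimated correlation and 0 with fry (2 and 5 at an unadjusted p under 0.05), and 5 to 11 without each sample, 4 to 9 of them among the 10. Cholesterol synthesis and cell cycle lists kept their calls in 25 of 27 alternatives each, all but the estimated correlation and fry, fat absorption genes in 23, macrophage markers in 22, goblet markers in 20, PPARa targets in 19, smooth muscle markers in 15, neuron markers in 14 and clock genes in 7, and T cell markers in 10 of 26. With array set 1 alone the camera direction turned for the fat absorption list (median -0.10) and the smooth muscle list (median -0.18). Over all lists, 825 list results kept their side of the threshold, 63 of them with a median of the other sign. The call was lost in 87 with the same camera direction and in 2 with the direction turned, and 24 gained one. Of 1592 gene results under alternatives, 1 had the other sign (Irgm2), 16 lost a call and 20 gained one. The array range difference within sets was 0.23 with an exact permutation p of 0.0167, against 0.135 over all samples. The other planned results near Ifng and by array set stayed on their side of the threshold. For results not noted as fitted on fewer samples, the cause was not tested. Signal over background limits the size of the differences of dim genes such as Ubd, Ccl5 and Cd8b1, which were not detected on every array.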

Other observations

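In this part the exact tests within array sets of the clock index, the cholesterol mean and the cell cycle mean, and the split counts for cell cycle genes and for unadjusted p-values were chosen only after the result was seen. Xenobiotic metabolism genes had 23 of 39 members higher (median 0.12, camera adjusted p = 0.0632), with a median of 0.22 in array set 1 and 0.03 in array set 2. The median was -0.002 (adjusted p = 0.815) without Ileum_WT_641, the array with the fewest probes detected, and the list passed in array set 1 alone (0.00153, against 0.742 in array set 2), with normexp without detection p-values (0.0464), and without Ileum_WT_640 (0.0256), Ileum_WT_644 (0.046, with a median of 0.05), Ileum_IFNgKO_647 (0.032) or Ileum_IFNgKO_649 (0.0324). The glutathione transferases Gsta2 (1.20 ± 0.26, SE) and Gsta3 (1.14 ± 0.21) passed 5% adjusted over that list alone. Gcg, which encodes proglucagon, the precursor of GLP-1, was higher by 1.06 ± 0.24 and passed adjusted over the enteroendocrine list alone, while the 22 measured enteroendocrine genes had a median of 0.08 (adjusted p = 0.444), 14 higher and 8 lower. None of these genes passed over all probes. Leaving out 1 sample in turn put the enteroendocrine median at 0.004 to 0.12.

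Among heat shock genes, Hspa1a, an inducible chaperone, was at 8.47 ± 1.15 in WT and 7.10 ± 0.29 in the knockout (SD, n = 5 each; limma adjusted p = 0.268) and Hsph1 differed by -0.80 ± 0.27 (SE), within a stress list whose median was -0.05, or 0.12 under median scaling (adjusted p = 0.52). Acly (1.07 ± 0.21), which makes cytosolic acetyl-CoA, and Scd2 (0.94 ± 0.20), a fatty acid desaturase, were chosen after their values were seen, and had adjusted p-values of 0.175 and 0.196. B cell markers had a median of 0.32 over 8 measured genes (adjusted p = 0.444), and 4 higher and 1 lower passed 5% adjusted over the list alone, among them Pou2af1 at 0.66 ± 0.23 and, as the lower one, Ltb at -0.56 ± 0.20. Leaving out 1 sample in turn put the B cell median at 0.20 to 0.37.

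Other splits of the 10 samples into 5 and 5 were run with the same design, 100 of the 126 possible. As many probes past 5% as the real 2 came from 3 of 100 splits, the real one included, under the 5% of splits set beforehand. This low share does not exclude chance, since splits were not balanced over array set and several counts were taken from them unadjusted. The highest of the other splits called 24 probes. That split set Ileum_WT_640, Ileum_WT_643, Ileum_IFNgKO_645, Ileum_IFNgKO_646 and Ileum_IFNgKO_647, which had the highest scores on the second principal component (19.5% of the variance), against the rest, and so points to a structure of the samples other than genotype. As many lists as the real 10 came from 12 of 100 splits, with 15 as the highest other, so chance is not excluded for the number of lists. The cell cycle mean of 0.234 was matched or passed by 7 of 100 splits, the real one included, with 0.366 as the highest other, so these splits do not exclude chance for that list. Of the other 6 splits 0 had 2 array set 1 samples on each side, and permuted within array sets the cell cycle mean, like the cholesterol mean, had an exact p of 0.0167, the smallest that 120 assignments allow, each for 1 list picked from 35.

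Higher cholesterol synthesis genes were the strongest list result. The weak array of Ileum_WT_641 is argued against as the source of the difference over both array sets, since the median was 0.435 without it against 0.494 with all samples. The difference within array set 1 rested in part on that array. Its list mean was 9.41, against 9.78 in Ileum_WT_640, 9.84 in Ileum_IFNgKO_645 and 9.93 in Ileum_IFNgKO_646. With the clock index as a covariate the mean difference was 0.518 ± 0.18 (SE), against 0.436 ± 0.11 without it. The relation of index and list within genotype thus did not account for the difference. The index itself differed between genotypes, so this cannot tell harvest at another time of day from genotype. A mean difference as large as 0.436 came from 2 of 100 splits, the real one included; the other, at 0.619, set array set 1 with Ileum_WT_642 against the remaining samples, so with array set fitted it rested on that sample, and the within-set medians of the real split were 0.33 and 0.60. An effect of IFNg genotype may underlie the higher list, as a hypothesis that no test here decides. Harvest time stays open, as do cage, litter and feeding state, which are not given in the labels. The estimated correlation between the list's genes (camera adjusted p = 0.617) stays open too. Within array sets the raw log2 intensity range was wider in the knockout (by 0.23, exact permutation p = 0.0167), and this was not tested as a source.

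The clock index itself, the mean of 9 genes such as Dbp and Per3 minus the mean of 4 such as Arntl and Nfil3, was -0.50 ± 0.34 in WT and 0.42 ± 0.66 in the knockout (SD, n = 5 each). The difference fitted with array set was 0.92 ± 0.31 (SE), with an exact permutation p within array sets of 0.0167, the smallest that design gives, and Ileum_IFNgKO_649 was highest at 1.53. Within genotype and array set the index and the cholesterol list mean were compared over 10 samples, the 1 relation tested (Pearson r = -0.25, permutation p = 0.487; Spearman rho = -0.552, permutation p = 0.104), and r was -0.175 without the 2 samples farthest in the index.

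The 8 measured interferon-inducible GTPases, of 17 on the array, were not lower as a group in mice without IFNg, apart from Igtp. Signals too near background to show a fall are argued against only for the 5 GTPase genes detected at a p under 0.01 on all 10 arrays. For 5 of these 5 the 95% interval excluded a fall of 1 log2 unit, Igtp included (-0.88 to -0.25). Genes that fell to background in the knockout would have been left out, so the test cannot speak for the dimmer members. Mice whose genotype is not as labelled cannot be excluded as the source of this lack of a fall. Ifng was detected in 0 of 5 knockout and 0 of 5 WT samples. A low level of IFNg in the unchallenged WT ileum, or other interferons that induce the same genes, may account for it; neither was tested.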
